A study of Mus musculus with 8 samples.

How the data were processed

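Gene expression was measured in mouse pre-iPSCs, cells that began reprogramming towards induced pluripotent stem cells and stalled before reaching pluripotency. Per the labels' protocols, the cells were grown in standard embryonic stem cell medium and kept with siRNA for 3 days before total RNA was extracted with Trizol and labelled with biotin. The 8 arrays fall into 3 groups by the siRNA named in the labels. Control arrays (n = 3) come from cells with siRNA against luciferase. 3XHMT arrays (n = 2) come from cells in which Ehmt1, Ehmt2 and Setdb1, which encode H3K9 methyltransferases, were targeted at once. Cbx3 arrays (n = 3) come from cells with siRNA against Cbx3, which encodes the heterochromatin protein HP1 gamma. The labels call the samples of a group biological replicates, without saying what was repeated.

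The deposited table holds log2 expression values for 45101 probe sets on 8 arrays, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarises probes, so that a shift shared by most genes on an array is removed. The version and settings of RMA are not given in the sources used here. Array medians lay between 5.87 and 5.90 on the log2 scale. The number of arrays limits the precision of every value, and signal close to background compresses fold changes.

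Probe sets were named through the platform annotation supplied with the table. It gave 1 gene symbol to 34945 probe sets and several to 932, while 9160 probe sets were not listed and stay unnamed. Of the probe sets with 1 symbol, 34741 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6 and 204 did not, and 0 symbols needed updating. That table served for names and for which genes neighbour each other. The 64 control probe sets entered no gene test. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. The targeted genes were also followed in a fit of all probe sets, since the bright Cbx3 probe sets carry a second symbol, the pseudogene Cbx3-ps5.

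Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), so that the 3 groups share 1 estimate of the spread with 5 residual degrees of freedom. The comparisons were 3XHMT against control, Cbx3 against control and 3XHMT against Cbx3. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene comes from this limma fit unless another is named.

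The groups, the tests, the rule for named genes and 19 gene lists were fixed before the data were examined. The lists held 770 entries of which 666 were measured: H3K9 methylation machinery, pluripotency, fibroblast and mesenchymal, epithelial, germline, 2-cell stage, trophoblast, primitive endoderm, imprinted, protocadherin clusters, cell cycle, p53 and senescence, interferon response, neural ectoderm, mesendoderm, Hox clusters, macrophage and blood, stress and unfolded protein response, and DNA methylation and Polycomb. Some genes stand in more than 1 list. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the 19 lists of a comparison.

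The rule for named genes took the 4 targets, the 8 largest rises and 8 largest falls among changed genes whose arrays did not overlap between the groups (5 each for 3XHMT against Cbx3, names of unnamed models and clones left out, and the 5 lowest unadjusted p where fewer than 5 passed), up to 4 members of each list with the lowest p, and a short set of pluripotency, epithelial, fibroblast and heterochromatin genes. Suv39h1, in that set, had no probe set of its own in the annotation used. Gbx2, Fgf4, Nr5a2, Esrp1, Grhl3, Krt18, Ovol2 and Klk1b16 fall outside the rule and were named after their values were seen, to spell out a count. The text gives the named genes that carry a comparison and leaves the others in counts.

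The arrays were checked for structure that the groups do not explain. The signal of the middle of 3 control probe sets for 18S ribosomal RNA divided them into 3 sets, called tiers here: control 1 and Cbx3 1 at 11.2 and 11.5, control 2, 3XHMT 1 and Cbx3 2 between 12.6 and 12.8, and control 3, 3XHMT 2 and Cbx3 3 between 9.98 and 10.2. The 5' probe set orders these sets alike. The 3' probe set does not part the first and last of them, at 10.3 and 10.6 against 10.6 to 11.1. Deviations from the group means correlated across genes by 0.51 to 0.74 between arrays of different groups in 1 tier, and by -0.66 to 0.22 otherwise. Replicate numbers, which the labels give, therefore pair control and Cbx3 arrays, with correlations of 0.51, 0.62 and 0.74. They do not pair the 3XHMT arrays, which correlated with same-numbered control arrays by 0.05 and -0.66. The tier was added to the fit as a block after the data were seen, and its values stand beside the counts, the lists and part of the named genes whose call it changes.

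The fit and camera were tested on simulated values with the real gene means and residual spread, drawn independently for each gene. In 5 runs with 200 changed genes among 18193, the fit of 3XHMT against control recovered 6.0%, 53.2%, 89.6% and 98.4% of changes of 0.5, 1, 2 and 3 on the log2 scale, and that of Cbx3 against control 16.4%, 71.2%, 92.8% and 98.4%. The share of false calls was 5.07% and 6.19%. A shift of 0.5 placed on the epithelial list in Cbx3 arrays was called in 20 of 20 runs, and the other lists in 1 of 360 tests. The real epithelial list had an estimated correlation of 0.11 between genes, so independent draws do not test camera under such correlation.

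The alternatives were another between-array normalization (cyclic loess), a filter on dim probe sets, other rules for genes with several probe sets, leaving out probe sets that can match several transcripts, an intensity trend and array weights in limma, fits of only the groups compared, the replicate number as a block, a minimum fold of 1.5, and leaving out each array. The tier block, the tiers that hold 3XHMT arrays alone, and the pairing of only control and Cbx3 arrays were added after seeing the data.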

Results

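Expression was profiled on 8 arrays of mouse pre-iPSCs after 3 days of siRNA, with 3 control arrays, 2 arrays of the 3XHMT group and 3 of the Cbx3 group. The design asks how gene expression in these stalled cells changes when the enzymes that place H3K9 methylation, or a protein that binds it, are targeted. Arrays of 1 group correlated across probe sets by 0.984 to 0.994. The main axis of a principal component analysis held 41.5% of the variance and set control 3, 3XHMT 2 and Cbx3 3, 1 of the tiers of the 18S ribosomal RNA control, apart from the other arrays. The next axis held 21.3%.

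The transcripts targeted by siRNA were examined first. Cbx3 signal fell in the Cbx3 arrays: the brightest probe set went from 13.18 ± 0.14 (SD, n = 3) in control to 11.96 ± 0.25 (SD, n = 3) on the log2 scale, 42.8% of control, with a limma adjusted p of 0.0453 over all probe sets. Another bright probe set stood at 37.9% of control (adjusted p = 0.0465), and the remaining one at 43.9%, outside the threshold (adjusted p = 0.0525; 0.00182 with the tier as a block). These probe sets are annotated to both Cbx3 and its pseudogene Cbx3-ps5. The dim probe set annotated to Cbx3 alone was at 82.9% of control (adjusted p = 0.988). Within the tiers, the brightest probe set was at 57.0%, 39.8% and 34.4% of the paired control.

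In the 3XHMT arrays, Setdb1 was at 63.2% of control, Ehmt2 at 66.8% and Ehmt1 at 79.6%. In the gene-level limma fit these differences were not past the threshold, at adjusted p = 0.339 for Setdb1 and 1.00 for both Ehmt genes. Once the tier was a block, Setdb1 passed (adjusted p = 0.0295), while Ehmt1 (0.131) and Ehmt2 (0.196) did not. Adjusted over all probe sets, as for Cbx3, Setdb1 did not pass with the block either (adjusted p = 0.0520). The dimmer Setdb1 probe sets stood at 95.3% and 60.9% of control and the dimmer Ehmt2 probe set at 75.5%. Within the tiers, Setdb1 was at 52.6% and 68.7% of control, Ehmt2 at 67.4% and 86.6%, and Ehmt1 at 72.3% and 78.2%, lower in both 3XHMT arrays in each case.

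**Figure D1:**
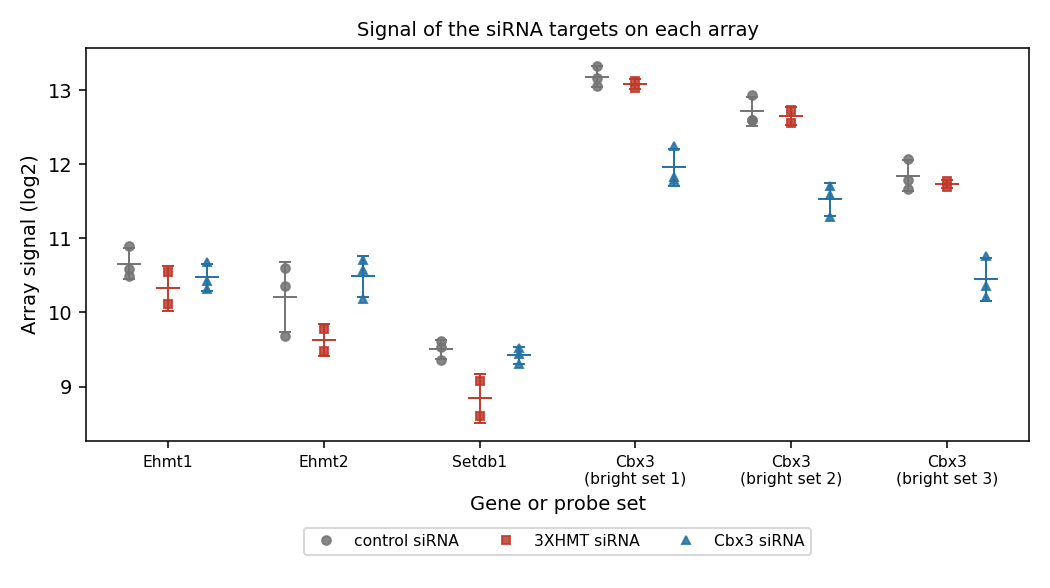
Array signal on the log2 scale (y axis) of the main probe sets of Ehmt1, Ehmt2 and Setdb1 and of the 3 bright Cbx3 probe sets (x axis), with 1 point per array and the mean ± SD of each group. The Cbx3 arrays lie below the control arrays at the bright Cbx3 probe sets, at 42.8%, 43.9% and 37.9% of control.

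A small set of genes was higher in cells with siRNA against the 3 methyltransferases, and the 8 largest rises started from control signals of 3.70 to 7.03 on the log2 scale. The largest rise was of Aass, an enzyme of lysine breakdown, from 5.46 ± 0.42 (SD, n = 3) to 10.75 ± 0.77 (SD, n = 2), which is 39.0-fold (limma adjusted p = 0.00308). The pluripotency genes Zfp42, Nanog and Dppa4 rose 8.54-fold, 7.01-fold and 5.89-fold (adjusted p = 0.0452, 0.0434 and 0.0135). Other large rises were those of Scgb3a1, a secretoglobin (7.16-fold), Defb1, a defensin (6.85-fold), Akr1c13, an aldo-keto reductase (6.72-fold), Mgat4c, a glycosyltransferase (6.44-fold), and Slc27a2, a fatty acid acyl-CoA synthetase (6.20-fold). The falls were of Tbx18, a T-box transcription factor (3.95-fold lower, adjusted p = 0.00716), the thioesterase gene Them4 (2.03-fold), Ppp1r9a, which encodes neurabin (2.01-fold), Oxr1 (1.87-fold) and Thbd, which encodes thrombomodulin (1.85-fold). Some of these values depend on the probe set. With each gene at its second probe set 9 of the 16 named calls were lost, among them Tbx18, at -1.33 on the log2 scale (adjusted p = 0.171). Of these, Zfp42, Nanog and Thbd kept their probe set and value and were lost through the adjustment alone (adjusted p = 0.0573, 0.0510 and 0.0573). Oxr1 differed by 0.019 on the log2 scale when probe sets that can match several transcripts were left out, Them4 by -0.030 and Defb1 by 1.64 (adjusted p = 0.0703) at their second probe set, and Ppp1r9a by -0.57 over the mean of its probe sets.

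In all, 42 of 18193 genes changed between 3XHMT and control, 37 higher and 5 lower, and 958 had an unadjusted p under 0.05. The groups separated without overlap at 16.4% of genes, where chance gives 20% for 2 against 3 arrays. Blocking on the tier gave a count of 320, with 158 higher and 162 lower, and it held all 42. The count rests on every array: it was 3 and 16 without 3XHMT replicates 1 and 2, 9, 8 and 20 without control replicates 1, 2 and 3, and 15, 15 and 22 without Cbx3 replicates 1, 2 and 3. Leaving out probe sets below the median signal left 5 genes. Of the 16 named changes, 2 (Aass and Mgat4c) passed under all 8 omissions and 7 under none: Zfp42, Akr1c13, Pcdhb21 and the falls of Them4, Ppp1r9a, Oxr1 and Thbd. Of the omissions, Tbx18 failed under that of 3XHMT replicate 1 (adjusted p = 0.0903). Zfp42 was lost with log2 changes of 2.49 to 3.70 and adjusted p of 0.0695 to 0.323, and the 4 falls with adjusted p of 0.0537 to 0.378. Nanog failed under 6 of the 8 (log2 changes of 2.59 to 3.03, adjusted p up to 0.323), Neurod1 under 7, Defb1 and Scgb3a1 under 4, Slc27a2 under 2, and Dppa4 without control replicate 1 or 2 (adjusted p up to 0.0746).

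Within the pluripotency list, 37 of 47 measured members were higher in 3XHMT than in control cells, and the list shifted upwards (camera adjusted p = 6.58e-05; adjusted p = 0.642 with an estimated correlation). Within the tiers the tally was less uniform: 59.6% and 57.4% of members were higher, with median differences of 0.080 and 0.11. Dppa4, Nanog and Zfp42 passed over all genes, and 5 members adjusted over the list alone, with Dppa2 and Gbx2 in addition. Dppa2 stood 2.68 ± 0.43 (SE) higher on the log2 scale with an adjusted p of 0.0682. Blocking on the tier, 7 members passed: Dppa2, Dppa4, Dppa5a, Gbx2, Nanog, Nr0b1 and Zfp42. No difference was resolved for the core reprogramming factors. Their log2 differences were 0.05 ± 0.19 (SE) for Pou5f1, 0.16 ± 0.56 for Sox2 and -0.12 ± 0.36 for Klf4. Those of Sox2 and Klf4 are too imprecise to exclude a change, and Pou5f1 signal was already 12.99 in control. Esrrb, another gene of the pluripotency network, differed by 0.16 ± 0.16 (adjusted p = 1.00).

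**Figure D2:**
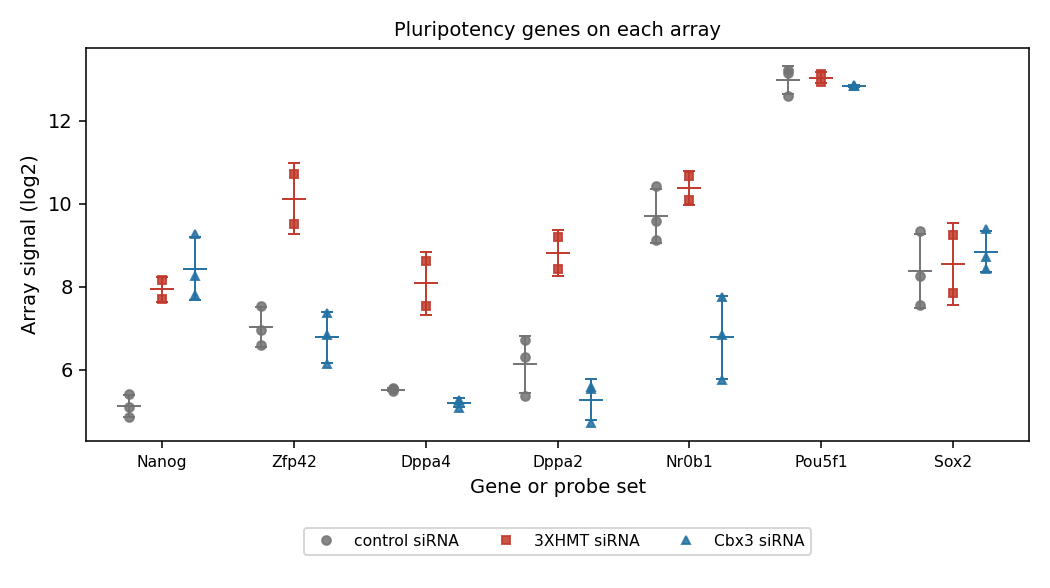
Array signal on the log2 scale (y axis) of 7 pluripotency genes (x axis), with 1 point per array and the mean ± SD of each group. Nanog is higher in both knockdowns (7.94 and 8.44 against 5.13 in control), Zfp42, Dppa4 and Dppa2 are high in the 3XHMT arrays, and Pou5f1 lies near 13 in all groups.

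The Hox clusters shifted downwards in 3XHMT cells, with 22 of 33 members lower (camera adjusted p = 0.0406), and the genes of the 2-cell stage embryo upwards, with 13 of 17 higher (adjusted p = 0.0485). With an estimated correlation their adjusted p was 0.736 and 0.642, and with the tier as a block 0.189 and 0.133. Both calls were also lost without dim probe sets, with cyclic loess and with the second probe set of a gene. The Hox call was lost without control replicate 1 (adjusted p = 0.221), control replicate 2 (0.161) or 3XHMT replicate 2 (0.591), and the 2-cell call without control replicate 1 (0.0732), control replicate 2 (0.161) or 3XHMT replicate 1 (0.304). By limma 0 members of either list changed over all genes (Hoxd13 and Usp17la with the block), and the unadjusted p was under 0.05 for 5 lower and 1 higher Hox genes and for 2 higher 2-cell genes. Hoxd13 was 1.80-fold lower (adjusted p = 0.277; 0.0395 with the block). The 2-cell genes Usp17la and Zfp809 were 1.95-fold and 1.41-fold higher (adjusted p = 0.105 and 0.307; 0.0258 and 0.0613 with the block) and passed adjusted over the list alone.

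Single members of other lists changed in 3XHMT cells. Neurod1, a neurogenic transcription factor, rose 4.74-fold (adjusted p = 0.0313) and Pcdhb21 rose 1.85-fold (adjusted p = 0.0434; a log2 change of 0.30 at its second probe set), while the imprinted gene Ppp1r9a and Thbd of the primitive endoderm list fell. With the tier as a block, Pcdhb20, Pcdhb21 and Pcdhb22, cell adhesion genes of 1 cluster, all passed, with Pcdhb20 4.07-fold higher (adjusted p = 0.136 without the block). The remaining lists had camera adjusted p of 0.0755 (protocadherin clusters), 0.104 (germline), 0.113 (epithelial), 0.263 (fibroblast and mesenchymal), 0.334 (both H3K9 methylation machinery and stress), 0.353 (imprinted), 0.386 (p53 and senescence), 0.468 (trophoblast), 0.680 (cell cycle, primitive endoderm, and DNA methylation and Polycomb), 0.690 (neural ectoderm, mesendoderm, and macrophage and blood) and 0.842 (interferon response). For primitive endoderm the median was 0.00 and the mean -0.05, with a downward test.

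Nanog was also higher in cells with siRNA against Cbx3, rising from 5.13 ± 0.27 to 8.44 ± 0.76 (SD, n = 3 each), which is 9.94-fold (limma adjusted p = 0.0151), but not Zfp42 or Dppa4. Zfp42 differed by -0.25 ± 0.40 (SE) and Dppa4 by -0.32 ± 0.24 on the log2 scale. The other large rises were of the lipoxygenase gene Alox15 (5.77-fold), the transcriptional coactivator gene Cited1 (3.99-fold), the innate immune receptor gene Tlr2 (3.84-fold), Palmd (3.82-fold), the prostaglandin synthase gene Ptgs2 (3.72-fold), Edil3 (3.63-fold) and Chil1 (3.56-fold). The largest falls were of Calcb, a calcitonin-related peptide gene (5.56-fold lower), Arpp21 (5.17-fold), the neuronal RNA-binding protein gene Elavl2 (4.13-fold), the cystine transporter gene Slc7a11 (3.70-fold), Tmem47 (3.63-fold), the basement membrane gene Nid1 (3.57-fold), the planar polarity gene Prickle2 (3.38-fold) and Pcdhb17 (3.32-fold).

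Between Cbx3 and control, 81 genes changed, 46 higher and 35 lower, and 1739 had an unadjusted p under 0.05. The groups separated without overlap at 14.3% of genes, where chance gives 10% for 3 against 3 arrays. With the tier as a block, which here equals the pairing of control and Cbx3 arrays, 1199 genes changed, 563 higher and 636 lower, with all 81 among them. The count without 1 array was 21, 16 and 34 without control replicates 1, 2 and 3, 22, 2 and 16 without Cbx3 replicates 1, 2 and 3, and 27 without either 3XHMT replicate. Of the 20 named changes, 0 passed under all 8 omissions in limma: 2, Plk3 and Psat1, were lost under each, and Tlr2, Palmd, Calcb, Slc7a11, Igf2 and Tspan32 under 7 of the 8, with adjusted p up to 0.216 over these genes. The fewest losses were those of Nanog, without control replicate 1 (adjusted p = 0.0615) or 2 (0.0656), and of Alox15 (0.0547), Cited1, Pcdhb17 and Ptgs2 (0.0505 each) without Cbx3 replicate 2. With each gene at its second probe set 8 of the 20 were lost, of which Tmem47 and Psat1 kept log2 changes of -1.84 and -0.67. There the log2 changes were -0.037 for Arpp21, 0.22 for Edil3, -0.37 for Nid1 and 0.98 for Ptgs2, with adjusted p of 0.0679 to 0.994.

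Epithelial genes were higher as a group in Cbx3 cells: 31 of 35 members, with a median of 1.23-fold (camera adjusted p = 9.79e-11; adjusted p = 0.274 with an estimated correlation). By limma 0 of the 35 passed over all genes, 11 passed adjusted over the list alone, and 14 higher and 1 lower member had an unadjusted p under 0.05. Blocking on the tier, 14 members rose, among them the adhesion genes Cdh1 and Epcam, the keratins Krt8 and Krt18, the splicing regulators Esrp1 and Esrp2 and the transcription factors Grhl1, Grhl3 and Ovol2. Epcam stood 1.97-fold higher (adjusted p = 0.187; 0.00550 with the block) and Cdh1 1.83-fold (0.490; 0.0305). Within the tiers the list's median difference was 0.54, 0.23 and 0.31. The fibroblast and mesenchymal list had a median difference of 0.02 (camera adjusted p = 0.972), with 23 of 42 members higher. With the block 2 members rose and 3 fell, among the latter Cdh2, 1.84-fold lower (limma adjusted p = 0.0601; 0.00614 with the block).

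**Figure D3:**
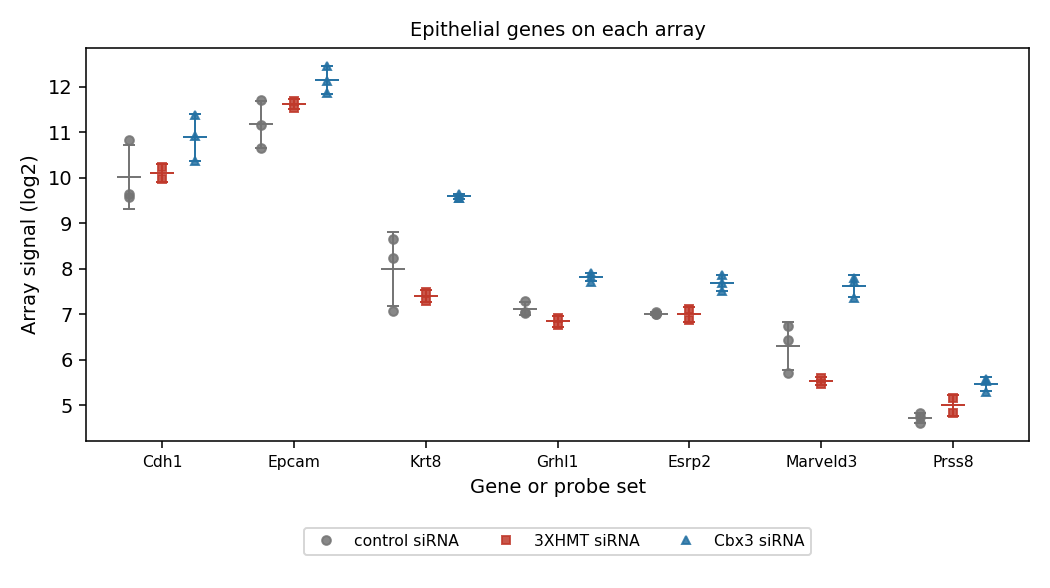
Array signal on the log2 scale (y axis) of 7 epithelial genes (x axis), with 1 point per array and the mean ± SD of each group. Group means are highest in the Cbx3 arrays for all 7 genes, for example 12.15 for Epcam against 11.17 in control and 11.62 in 3XHMT arrays.

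Other lists moved in Cbx3 cells. Trophoblast genes were higher, in 22 of 32 members (camera adjusted p = 0.00510), with Gata2 and Tinagl1 1.55-fold and 1.41-fold higher (adjusted p = 0.120 each; 0.0126 and 0.0259 with the block), and interferon response genes were higher in 30 of 41 (adjusted p = 0.0223). Protocadherin genes were lower in 17 of 23 (adjusted p = 0.00606), neural ectoderm genes in 24 of 38 (0.0223) and the H3K9 methylation machinery in 16 of 26 (0.0424; 0.0523 with the tier as a block). Pcdhb17 and Pcdhb19 stood at 5.23 to 5.83 in control, below the array medians of 5.87 to 5.90. The protocadherin call rests on dim signal, since without dim probe sets too few members of the list remained to test it. In that fit 0 lists passed as lower. With an estimated correlation the adjusted p was 0.730 for the trophoblast, interferon, neural and H3K9 lists and 0.274 for protocadherins. By limma Pcdhb17 alone changed over all genes among these lists, with 7 trophoblast, 4 interferon and 4 H3K9 members and 1 higher and 8 lower neural members at an unadjusted p under 0.05. Adjusted over the list alone, 2 trophoblast genes, 2 protocadherin genes, and 1 higher and 4 lower neural genes passed. The block called 5 trophoblast genes higher and 1 lower, 1 neural gene higher and 5 lower, and 2 protocadherin and 2 H3K9 genes lower. These 2 H3K9 genes were Kdm7a and Phf8, which encode histone demethylases, so the calls do not show a fall of methyltransferase genes. The neural genes Stmn2 and Nefl stood 3.99-fold and 4.18-fold lower (adjusted p = 0.0823 and 0.105; 0.00179 and 0.00294 with the block). Within the tiers the medians were 0.32, -0.10 and 0.17 for interferon genes and 0.036, -0.20 and -0.21 for neural genes. The interferon call was lost without control replicate 1 (adjusted p = 0.280), control replicate 3 (0.0590) or Cbx3 replicate 1 (0.255), the neural call without control replicate 2 (0.349) or Cbx3 replicate 3 (0.0871), and the H3K9 call without control replicate 3 (0.373) or Cbx3 replicate 1 (0.207).

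The pluripotency list did not shift in Cbx3 cells (camera adjusted p = 0.323, with a median of 0.00, a mean of -0.05 and a downward test). Besides Nanog, 5 members were lower over the list alone: Nr0b1, a nuclear receptor gene (7.64-fold lower, adjusted p = 0.0601), Eras (2.23-fold), Phc1 (1.57-fold), Fgf4 and Nr5a2. With the tier as a block, 8 members fell, these 5 among them, and Nanog rose. The imprinted genes Igf2 and Tspan32 rose 2.84-fold and 2.31-fold (adjusted p = 0.0368 and 0.0325) but differed by 0.14 and 0.086 on the log2 scale at their second probe set (adjusted p = 0.940 and 0.990). Both calls were lost under 7 of the 8 omissions of an array (adjusted p up to 0.165 and 0.145). Plk3 of the p53 list rose 1.71-fold (0.0390) and Psat1, of serine synthesis, fell 1.61-fold (0.0491), each lost under all 8 omissions (adjusted p up to 0.179 and 0.216). The lists not yet given had camera adjusted p of 0.109 (Hox clusters), 0.171 (cell cycle), 0.173 (p53 and senescence), 0.208 (imprinted), 0.289 (2-cell stage), 0.386 (primitive endoderm), 0.436 (mesendoderm) and 0.972 (germline, macrophage and blood, stress, and DNA methylation and Polycomb). For germline the median was -0.01 and the mean 0.06, and for macrophage and blood genes 0.05 and -0.05, both with an upward test.

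The knockdowns were also set against each other, which tests the difference between them. Relative to Cbx3 cells, 3XHMT cells had higher Aass (24.5-fold), Nr0b1 (12.1-fold), Dppa2 (11.6-fold), Akr1c18 (11.5-fold), Zfp42 (10.1-fold) and Dppa4 (7.34-fold), with limma adjusted p between 0.00304 and 0.0324. They had lower Cavin2 (5.30-fold), Krt8 (4.57-fold), Palmd (4.27-fold), Marveld3, a tight junction gene (4.26-fold), and Crispld2 (4.09-fold), with adjusted p between 0.0150 and 0.0376. Nanog, higher in both knockdowns, differed between them by -0.50 ± 0.39 (SE) on the log2 scale (adjusted p = 0.761). In all 275 genes differed, 147 higher and 128 lower in 3XHMT cells, and 2075 had an unadjusted p under 0.05.

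Between the knockdowns 1660 genes differed with the tier as a block, 854 higher and 806 lower, including all 275. The count was 24 and 22 without 3XHMT replicates 1 and 2, and 77, 67 and 112 without Cbx3 replicates 1, 2 and 3. Of the 29 named differences, 3 (Aass, Dppa4 and Pcdhb17) passed under all 8 omissions and 0 were lost under all 8 in limma. With each gene at its second probe set 10 of the 29 were lost, among them Cavin2, Marveld3, Hoxd13 and Pcdhb21, which differed by -1.79, -0.75, -0.41 and 0.20 on the log2 scale (adjusted p = 0.264, 0.200, 0.653 and 0.854). Of the 10, Col4a2 and Tinagl1 kept their probe set and value (adjusted p = 0.0502 and 0.0577), and Nefl stood at 2.36 (0.126). Groups separated without overlap at 26.7% of genes, where chance gives 20% for 2 against 3 arrays.

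As lists, pluripotency genes were higher in 3XHMT than in Cbx3 cells (31 of 47, camera adjusted p = 8.69e-05), and 6 members passed: Dppa2, Dppa4, Eras, Nr0b1, Phc1 and Zfp42. Epithelial genes were lower (30 of 35, adjusted p = 6.00e-11), and Grhl1, Krt8 and Marveld3 passed. Protocadherin genes were higher (18 of 23, adjusted p = 4.18e-05), with Pcdhb17, Pcdhb20 and Pcdhb21 passing, and neural genes were higher (23 of 38, 0.0470; 0.0999 with the tier as a block), with Neurod1 6.59-fold and Nefl 7.43-fold higher. The 3 protocadherin genes named here stood at only 3.71 to 5.38 in the Cbx3 arrays, below the array medians of 5.87 to 5.90. Without dim probe sets too few members of their list remained to test it here as well. Trophoblast genes (25 of 32, 0.00108) and Hox genes (26 of 33, 0.000828) were lower. With an estimated correlation the adjusted p was 0.137 for the epithelial and protocadherin lists, 0.542 for pluripotency, trophoblast and Hox genes and 0.552 for neural genes. The Hox call was lost without 3XHMT replicate 2 (adjusted p = 0.110), and the neural call without 3XHMT replicate 1 (0.257), Cbx3 replicate 3 (0.137) or control replicates 2 (0.0522) or 3 (0.0714). The other 13 lists had camera adjusted p from 0.0722 to 0.801, of which p53 and senescence (0.0722) passed with the tier as a block (0.0456). Median and mean differed in sign for macrophage and blood genes (-0.01 and 0.07) and for DNA methylation and Polycomb genes (-0.05 and 0.04), both with an upward test.

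Across the 18193 genes, the log2 changes of the knockdowns against the shared controls correlated by r = 0.163, and genes are not independent replicates. Simulated unchanged arrays, controls included and drawn independently, gave a mean r of 0.447, and 0.448 with the spread left after the tier block. That r is set by the group sizes and the shared control group. A change in only 1 knockdown lowers r, so an observed r below it does not measure disagreement. Without control replicates 2 and 3 the observed r was 0.349 and 0.305, and without 3XHMT replicate 1 it was 0.0359. The covariance was 0.0115, against 0.0226 in that simulation, and against 0.00909 when the simulated spread was that left after the tier block. With the block in the estimates as well, the covariance was 0.00652 against 0.00908 simulated, and r was 0.0907 against 0.427. Of the changed genes, 3 were higher in both knockdowns (Klk1b16, Nanog and Ptgs2) where independent lists would share 0.0936, 1 was lower in both (Tbx18; 0.00962), and 0 went opposite ways (0.0838). At an unadjusted p under 0.05 in both limma comparisons these counts were 86, 107 and 106. With the tier as a block they were 31, 32 and 55, where independent lists would share 4.89, 5.66 and 10.5. Part of the shared calls may rest on the shared control arrays, which are too few to divide. Of the 42 genes changed in 3XHMT cells 34 also differed between the knockdowns, as did 50 of the 81 changed in Cbx3 cells. The genes were chosen on arrays that also enter the comparison between the knockdowns, so a high share follows in part from the choice.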

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

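The fit of probe sets without a gene name was not among the planned comparisons and was chosen after the data were seen.

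Some probe sets that the annotation used here does not list also passed the limma threshold, in a fit of all probe sets. There were 5 in 3XHMT against control, all higher, with log2 changes from 2.15 to 5.44, and 3 in Cbx3 against control, all higher, from 1.13 to 1.61. These calls were 0.055% and 0.033% of the unlisted probe sets, against 0.057% and 0.083% of the probe sets with 1 symbol, so they were not more frequent. The unlisted probe sets called drew attention because they lie outside the gene comparisons and differ from the control arrays. Their genes were not identified here, and no explanation was tested.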

How the results depend on the processing

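Fits with the tier block, with the 2 tiers that hold 3XHMT arrays, and with the pairing of only control and Cbx3 arrays were chosen after seeing the data; the others were planned. Of the planned values of whole comparisons, 146 kept their size within 1.5 times or their side of the threshold and 48 moved; of those of lists, 943 kept their side, 56 lost it, 23 gained it and 1 reversed; of those of named genes, 4662, 382, 99 and 2. For the added fits, 15 values of whole comparisons kept, 8 moved and 2 gained the threshold; 119 of lists kept their side, 9 lost it and 5 gained it; 523 of named genes kept it and 208 gained it. The main counts were 42, 81 and 275 genes (3XHMT against control, Cbx3 against control, 3XHMT against Cbx3) and 3, 6 and 6 lists. Of 311 named gene results only 16, 20 and 29 passed in the main fit, and of 57 list results only those 3, 6 and 6. Every loss therefore fell on these calls, and most values that kept their side were non-calls that stayed so. The cause was not tested unless stated.

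Without dim probe sets the counts were 5, 43 and 171 genes, with 1 list for 3XHMT and 3 for Cbx3 against control. With the second probe set of a gene they were 24 genes for 3XHMT against control, 165 between the knockdowns, and 1 list for 3XHMT against control. Cyclic loess gave 1 list there. Array weights gave 5 lists there and 130 genes for Cbx3. Fits of only the 2 groups compared, with fewer arrays, gave 10 and 27 genes against control. With an estimated correlation 0 lists passed in each comparison, and 2 lists had at least 75% of members on 1 side for Cbx3 against control.

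The replicate block by the numbers in the labels gave 97, 312 and 655 genes and 5 lists for 3XHMT against control. These numbers do not pair the 3XHMT arrays. The replicate block on control and Cbx3 arrays only gave 1448 genes. The tier block gave 320, 1199 and 1660 genes and 1 list for 3XHMT against control, and the 2 tiers with 3XHMT arrays 301, 520 and 1272 genes. Setdb1 passed under both, at -0.73 and -0.73 on the log2 scale, but differed by -0.069 with the second probe set or without probe sets that can match several transcripts.

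Leaving out 1 array gave 3 to 22, 2 to 34 and 22 to 273 genes, 1 to 5 lists for 3XHMT against control, and a correlation between the knockdowns of 0.0359 to 0.349 (0.163 with all arrays). A lone remaining 3XHMT array is assumed to vary like the other groups. The reversed values were Igf2 between the knockdowns (0.062 with the second probe set), Oxr1 in 3XHMT cells (0.019 without probe sets that can match several transcripts) and the cell cycle list in 3XHMT cells, whose median was -0.16 without 3XHMT replicate 2 and 0.23 without 3XHMT replicate 1. Beyond the lower gene counts without dim probe sets given above, how far signal over background limits these calls was not tested.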

Other observations

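The tests below were chosen after the result was seen, except the counts of splits of the arrays without a block and the neighbour test of the genes changed after Cbx3 knockdown.

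Members of the p53 and senescence list moved both ways after Cbx3 knockdown. Adjusted over the list alone, 2 members were higher (Btg2 and Plk3) and 5 lower (Ei24, Fas, Sesn1, Trp53inp1 and Zmat3) by limma, and with the tier as a block 2 rose and 7 fell. The block also called 6 imprinted genes higher after Cbx3 knockdown, namely Asb4, Igf2, Peg10, Phlda2, Sgce and Tspan32, and Ndn lower. Of the stress list, Hspa1a and Hspa1b, which encode heat shock proteins, and Nqo1 and Srxn1, of the oxidative stress response, rose with the block, while Asns, Phgdh, Psat1 and Vldlr fell. These genes were named after their values were seen.

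Arrays of different groups deviated together in 3 sets that match the tiers of the 18S ribosomal RNA control. The lowest correlation within a tier exceeded the highest between tiers by 0.288, as a technical batch shared by the arrays of a tier would give, and a difference between cultures grown together may do the same. The tier is no group of the design, so no biological explanation was tested. Other splits of the 6 control and Cbx3 arrays gave at most 0 changed genes by limma (1875 at an unadjusted p under 0.05) where the real split gave 81 (1739 unadjusted, fewer than that other split), with 1 of 10 splits as large. With pairs as a block, a pairing added after the data were seen, the real split gave 1448 (3813 unadjusted) and the other splits that part all pairs at most 0 (369 unadjusted), with 1 of 4 as large. For lists, 2 of 10 splits reached the 6 of the real one, and control 1, control 3 and Cbx3 2 against the rest gave 7; in each case the splits are too few for a share under 0.05.

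Zfp42, Dppa4, Dppa2 and Nanog were higher after 3XHMT knockdown. The lowest of the 8 within-tier differences was 1.72 on the log2 scale. These genes were picked for their rise, and at each of them every 3XHMT array lay above every control array. Any pairing of arrays would have given large differences, so this decides nothing about a batch shared within a tier. Over the whole pluripotency list the within-tier medians were 0.080 and 0.11. A share of fully reprogrammed cells in the cultures stays open: 17 pluripotency genes with low control signal had a median change of 0.30, with a 95% bootstrap interval of 0.04 to 1.63, but this set holds the 4 genes themselves and so decides nothing. The other 13 had a median of 0.16. An effect of the knockdown within the stalled cells is another open hypothesis.

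Epithelial genes were higher after Cbx3 knockdown. A batch that adds alike to all arrays of a tier cancels from this comparison, because each tier holds 1 control and 1 Cbx3 array. The within-tier medians, of which the lowest was 0.23 on the log2 scale, add no separate test. They come from the same arrays, and the list was picked for its rise. A lower share of the main cell type stays open. The epithelial median exceeded the neural median by 0.34, with a lower bound of 0.24. However, the neural gene Stmn2 stood at 12.4, 12.4 and 13.1 on the control arrays. Neural genes may thus mark the main cells themselves and fall with their share, so this difference cannot decide the question. Fewer fibroblast-like cells cannot be told apart from a change within cells, because the interval of the fibroblast list's median, -0.065 to 0.12, holds 0. A knockdown effect on epithelial genes may therefore be 1 of several causes.

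Whether changed genes lie near each other was tested against 10000 random draws of genes, with a window of 500 kb and the RefSeq table of assembly GRCm38.p6. Of 37 genes higher after 3XHMT knockdown, 4 had another within the window (1.11 by chance, permutation p = 0.0962), and with the tier as a block 32 of 157 (19.04 by chance, permutation p = 0.0191, 0.0668 adjusted over 7 sets). Of 80 changed after Cbx3 knockdown 4 had one changed the same way (2.65 by chance, permutation p = 0.380). Among 561 genes higher after Cbx3 knockdown with the tier as a block, 288 had such a neighbour, against 195 by chance and 234 for random genes drawn to the same local gene density (permutation p = 2e-04). Of 633 lower genes 220 had one against 239 by chance (permutation p = 0.909), without a draw matched on density. A stricter count of the higher genes left out probe sets that can match several transcripts and neighbours with the same name stem, and found 159 of 418 against 108 by chance, without matching on density (permutation p adjusted over 7 sets = 0.00070). For 3XHMT with the block this count was 15 of 131 against 12.2 (permutation p = 0.289). No draw was matched on signal level, so an excess tied to which genes are expressed in these cells is not excluded. A hypothesis is that genes raised by Cbx3 depletion share chromosome neighbourhoods, and a repeat in other cultures would test it.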
